A study of Homo sapiens with 16 samples.

How the data were processed

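The series holds RNA sequencing of human embryonic stem cells (line H9) and of neural progenitor cells derived with drugs, before and at day 2 after the label Ngn2, in 16 libraries. Cells were isolated by fluorescence-activated sorting, per the labels' protocols. The authors deposited 1 table of TPM values (transcript shares scaled by length to a fixed total), 1 column per library with no pooling. STAR, RSEM and the human genome build hg19 are named, without versions, per the submitters' processing notes; the annotation and any filter are not given in the sources used here. Each column of the deposited TPM table sums to 1000000 over the genes listed, so a gene's TPM depends on all others in its library and on their assigned lengths. TPM keeps no depth, so the depth per library is unknown and no counting error or detection limit can be given. Because no counts were given, an exact 0 is described as listed at 0, and no fold is given between 2 groups where 1 is wholly at 0. Differences of responses that rest on such a group are given in log2(TPM + 1) with a note, and depend on the added 1. Transcripts of near-identical gene copies (metallothioneins such as MT1G, ORM1, the IFITM family) share reads, and their values are uncertain.

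The table has 23686 genes; 1 gene with a value that is not a number in 1 library was left out, leaving 23685, of which 20669 have a current approved symbol. Genes with at least 1 TPM in at least 2 of the 16 libraries (15230) were tested. Values were log2(TPM + 1). Groups and replicate numbers came from the sample titles, and every library had its own column. No coordinates are given, since the reference at hand is of another build. No pair of libraries looked like the same library deposited more than once, since at most 2.246% of values were identical between libraries of a group. Some genes at 0 in 1 library had at least 10 TPM in the others of its group (3 to 18 per group), and none of them is named in the text.

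Differences were computed in R 4.3.3 with limma 3.58.1 (linear models with an intensity trend and empirical Bayes moderation) on all 16 libraries in 6 groups, which share 1 estimate of each gene's spread with 10 residual degrees of freedom. The 12 contrasts were the response of each population (Ngn2-labelled minus starting cells), the 3 pairs of starting populations, the 3 pairs of Ngn2-labelled groups and the 3 differences between responses. A gene counts as higher or lower where its Benjamini-Hochberg adjusted p over all genes of a contrast is under 0.05 and its log2 difference is at least 1 in size. Adjusted p-values in the text are from limma for genes and from limma's camera for lists, two-sided in both cases.

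Before the data were examined, 21 gene lists were fixed: pluripotency, neural progenitor, forebrain patterning, midbrain and isthmus patterning, HOX genes, neural crest, peripheral and sensory neuron, proneural cascade, pan-neuronal, cortical excitatory neuron, GABAergic neuron, motor and monoaminergic neuron, Notch pathway, WNT feedback targets, TGF-beta family targets, cell cycle, stress and immediate early genes, and the other-cell-type lists of mesoderm and endoderm, surface epithelium, fibroblast and mesenchyme, and glia. The contrasts, thresholds, alternatives and rule for named genes were fixed at the same time. Camera compares the members of a list with all other genes. It was run with a preset correlation between genes of 0.01 and again with a correlation estimated from the data, and p was adjusted over the 21 lists of a contrast. The preset correlation treats list members as nearly independent, so both p-values are given wherever the call was lost.

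The rule for named genes took NEUROG2 and EMX1, among others, in every comparison. From each list it took up to 3 members past the thresholds with the largest log2 difference and a mean of at least 5 TPM in the higher group. It also took the 5 largest rises and the 5 largest falls outside the lists with at least 10 TPM in the higher group and libraries that do not overlap between groups. For a difference of responses the last condition was a mean of at least 10 TPM in the highest of the groups. Clone names and small RNAs were left out of the latter part, and genes that repeat across comparisons were partly left out of the text. Some genes that the rule selects are not reported here, and counts of calls for named genes leave them out.

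The method was tested on simulated data with 200 changed genes among 15230. The changed genes, and the lists for camera, were drawn from genes with a mean log2(TPM + 1) of at least 3. The shares below therefore do not cover genes at lower levels. For the H9 response, 65% of genes changed by 1 log2 unit passed the adjusted p and 33% passed both thresholds, and 95% of those changed by 2 passed both. For the SLC response the shares were 77%, 45% and 92%, and for the difference between the SLC and H9 responses 38%, 25% and 82%. Of the unchanged genes 11, 3 and 9 passed the adjusted p, and 6, 2 and 7 passed both. Camera recovered the 1 shifted list, and 0 of the unshifted lists passed. Genes were simulated independently of each other, whereas the estimated correlation was 0.456 for HOX genes and 0.371 for proneural genes. The simulation therefore does not show how often camera with the preset correlation calls such correlated lists falsely.

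Titles share replicate numbers across groups. Deviations of same-numbered libraries from their group means correlated at 0.52 to 0.56 across genes in all 3 pairs of the Ngn2-labelled SL and SLC groups. The numbers were therefore taken to pair these 6 libraries, from the data and not from any label. No other pair of groups had 3 or more pairs that all exceeded 0.1. Pairs of groups that share only 2 numbers could not meet this. Among them, the SL and SLC starting cells had correlations of 0.28 and 0.36 and were treated as unpaired. Alternatives were a pseudocount of 0.1, no filter on low values, a filter of at least 5 TPM, TPM rescaled per library by the median ratio to the geometric mean, quantile normalization, a fit of the groups concerned alone, the replicate block, and each library left out in turn. Where a group was left with 1 library, it was assumed to vary like the others. Rescaling by the median ratio used 11072 genes with factors from 0.7472 to 1.17, and moved the median log2 difference of all genes in the SLC response from 0.363 to 0.012. Splits of higher and lower genes under a rescaling are given where they moved the share of higher genes by more than 10 percentage points.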

Results

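RNA was sequenced from human cells in 16 libraries that fell into 6 groups by their labels. The starting populations were the human embryonic stem cell line H9 (2 libraries, numbered 1 and 2) and a pair of populations labelled SL (2 libraries, numbered 1 and 3) and SLC (3 libraries). The labels describe the starting populations only as human embryonic stem cells or as neural progenitor cells obtained with drugs, and they do not spell out SL or SLC. The other 3 groups, of 3 libraries each, carried Ngn2 and day 2 in their labels and are called Ngn2-labelled H9, SL and SLC here. Neurogenin-2 (Ngn2, human gene NEUROG2) is a proneural transcription factor that turns stem cells into neurons when it is forced on, and the cells were sorted by fluorescence before RNA was taken. SL replicate 2 and H9 replicate 3 were not analysed here.

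The values were TPM, a length-scaled share of each library's transcripts, for 23685 genes. They keep no depth, so the depth of each library is unknown. Between 12549 and 13851 genes reached 1 TPM in a library. Pearson correlations across genes, which are not independent replicates, were 0.965 to 0.994 between libraries of a group and 0.815 to 0.965 between groups. The 100 most abundant genes held 43.37% to 49.92% of the TPM in the SLC libraries and 28.97% to 30.63% in the Ngn2-labelled SLC libraries. Every TPM value below is a group mean ± SD, with n = 2 for H9 and SL and n = 3 for the other groups. Each log2 difference is on the log2(TPM + 1) scale with its standard error, and understates the change of genes at low levels. The labels do not say that libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

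**Figure D1:**
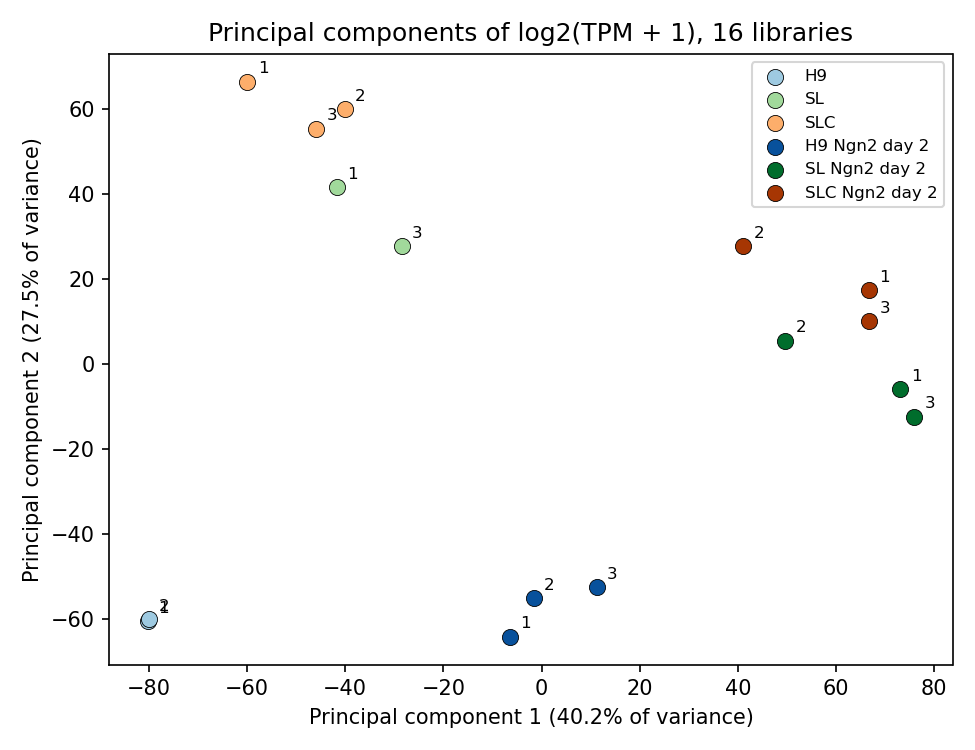
Principal components of log2(TPM + 1) over the genes tested, component 1 (40.2% of the variance) on the horizontal axis and component 2 (27.5%) on the vertical axis, in component score units. Each point is 1 library, coloured by group and marked with its replicate number; on component 1 the Ngn2-labelled libraries lie to the right of the libraries of their own starting cells.

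NEUROG2, the factor named in the labels, was measured first. It was at 0.04 and 0.05 TPM in the H9 libraries and at 15.94, 8.19 and 6.57 TPM in the Ngn2-labelled H9 libraries. In SL it was at 9.16 and 4.21 TPM, against 0.43, 0.36 and 0.45 TPM in the Ngn2-labelled SL libraries. In SLC it was at 2.48, 4.25 and 2.8 TPM, against 0.44, 1.13 and 0.56 TPM in the Ngn2-labelled SLC libraries. NEUROG2 thus rose with the label in H9 (log2 difference 3.34 ± 0.34, limma adjusted p = 8.1e-06) and was lower with it in SL (-2.36 ± 0.34, limma adjusted p = 0.00012) and SLC (-1.29 ± 0.30, limma adjusted p = 0.0027). The labels do not give the species or sequence of the introduced factor and the table has no entry for a transgene, so these values do not check the labels.

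EMX1, a homeobox factor of the developing forebrain, was also followed in every group because the series concerns cofactors of Ngn2. EMX1 was at 3.68 ± 0.0424 TPM in H9, 2.35 ± 1.1 in SL and 0.0167 ± 0.0289 in SLC. In the Ngn2-labelled libraries it was at 0.83 ± 0.358 TPM (H9), 0.28 ± 0.125 (SL) and 0.0767 ± 0.0289 (SLC). It fell in H9 (log2 difference -1.37 ± 0.21, limma adjusted p = 0.00024) and SL (-1.35 ± 0.21, limma adjusted p = 0.00022), while the SLC difference of 0.08 ± 0.19 did not pass (limma adjusted p = 0.73).

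The first comparisons asked how the 3 starting populations differed before Ngn2. SL cells had lost the pluripotency programme of H9 and expressed neural progenitor and anterior forebrain genes. POU5F1, the core pluripotency factor, was at 2388 ± 129.6 TPM in H9 and 13.2 ± 1.25 TPM in SL. TDGF1, a Nodal co-receptor of stem cells, was at 570.3 ± 37.8 and 0.185 ± 0.0778 TPM. SIX3, an anterior forebrain and eye field factor, was at 0.17 ± 0.127 TPM in H9 and 282 ± 92.7 TPM in SL. FEZF1, a forebrain zinc finger factor, was at 2.05 ± 0.785 and 290.1 ± 5.08 TPM. Of the 15 forebrain patterning genes tested, 11 were higher in SL (11 adjusted over the list alone, camera adjusted p = 3.59e-07), among them SIX6 (135 ± 126 TPM in SL). Of 23 neural progenitor genes, 19 were higher and 1 lower (19 and 1 adjusted over the list alone, camera adjusted p = 2.62e-08). SOX21 was at 132 ± 21.1 TPM and ZNF521 at 76.4 ± 7.08 TPM in SL against 0.67 ± 0.141 and 1.25 ± 0.113 TPM in H9.

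Of 17 pluripotency genes, 14 were lower in SL (14 adjusted over the list alone, camera adjusted p = 9.1e-12). Of 14 TGF-beta family targets 11 were lower and 2 higher (11 and 2 adjusted over the list alone, camera adjusted p = 7.92e-05). LEFTY1, a Nodal antagonist, was at 309 ± 25 TPM in H9 and 0.245 ± 0.247 TPM in SL, and NODAL itself at 42.7 ± 1.05 and 0.835 ± 0.106 TPM. Epithelial genes that stem cells also express were lower, with CDH1 (E-cadherin) at 76.5 TPM in both H9 libraries and 1.62 ± 1.94 TPM in SL. In all, 5 of 10 surface epithelium genes were lower and 1 higher (5 and 1 adjusted over the list alone, camera adjusted p = 0.0235, adjusted p = 0.568 with an estimated correlation). In the glia list 6 of 9 genes were lower (6 adjusted over the list alone, camera adjusted p = 0.000332, adjusted p = 0.0898 with an estimated correlation). No HOX gene passed in either direction (0 of 27 in limma, 0 adjusted over the list alone). Outside the lists the imprinted growth regulator DLK1 (3.2 ± 0.516 to 1926 ± 751 TPM) and IGFBP5 (0.325 ± 0.0778 to 289.8 ± 71.5 TPM) were among the largest rises. The stem cell transcript ESRG (495 ± 38.8 to 0.25 ± 0.127 TPM) and the neuropeptide gene GAL (238 ± 5.11 to 1.2 ± 0.53 TPM) were among the largest falls. Limma called 1725 genes higher and 1679 lower in SL than in H9.

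SLC cells had also lost pluripotency genes, and they expressed posterior HOX and WNT-responsive genes. HOXB9, a homeobox gene of the trunk, was at 0.02 ± 0.0283 TPM in H9 and 532 ± 94 TPM in SLC, HOXB3 at 0.015 ± 0.0212 and 180.5 ± 69.9 TPM, and HOXB8 at 0.06 ± 0.0849 and 93 ± 34.4 TPM. Of 27 HOX genes, 22 were higher (23 adjusted over the list alone, camera adjusted p = 2.76e-15, adjusted p = 0.112 with an estimated correlation). CDX2, a caudal homeobox factor and WNT target, was at 0.02 ± 0.0283 and 203 ± 95 TPM, and SP5, a WNT-induced zinc finger factor, at 0.84 ± 0.0424 and 194 ± 27 TPM. Of 15 WNT feedback targets 11 were higher and 1 lower (11 and 1 adjusted over the list alone, camera adjusted p = 1.5e-05). FGF17 and FGF8, ligands of the midbrain-hindbrain boundary, were higher, FGF17 at 0.41 ± 0.156 TPM in H9 and 198 ± 71 TPM in SLC. They were among 5 of 8 midbrain and isthmus genes that were higher (5 adjusted over the list alone, camera adjusted p = 0.00617, adjusted p = 0.111 with an estimated correlation).

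Neural progenitor genes were higher in SLC for 12 of 23 members and lower for 2 (12 and 2 adjusted over the list alone, camera adjusted p = 0.000344, adjusted p = 0.21 with an estimated correlation). POU3F2 was at 11.8 ± 3.11 TPM against 0.155 ± 0.106 TPM in H9. The cell adhesion gene NCAM1 was at 155 ± 17.5 TPM against 1.66 ± 0.191 TPM, and WLS, which carries WNT proteins to the cell surface, at 204 ± 12.5 against 1.85 ± 0.636 TPM. Of 17 pluripotency genes 14 were lower (14 adjusted over the list alone, camera adjusted p = 2.64e-12), with UTF1 at 142 ± 18.1 TPM in H9 and 0.203 ± 0.17 TPM in SLC. Of 14 TGF-beta family targets 11 were lower (11 adjusted over the list alone, camera adjusted p = 0.000198). In the surface epithelium list 7 of 10 genes were lower and 1 higher (7 and 1 adjusted over the list alone, camera adjusted p = 0.00438, adjusted p = 0.387 with an estimated correlation). The limma totals were 1349 genes higher and 2181 lower, or 1786 and 1832 after quantile normalization.

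Set directly against each other, the drug-derived populations parted along the head-to-trunk axis. SL held the anterior genes: FEZF1 was at 290.1 ± 5.08 TPM in SL and 0.0933 ± 0.0289 TPM in SLC, SIX3 at 282 ± 92.7 and 0.04 ± 0.04 TPM, and PAX6, a forebrain and eye factor, at 26.6 ± 10.7 and 0.263 ± 0.135 TPM. The WNT receptor gene FZD5 was at 226 ± 92.6 and 0.917 ± 0.379 TPM. SLC held the posterior ones, with HOXB8 at 0.03 ± 0.0424 TPM in SL and 93 ± 34.4 TPM in SLC, while HOXB9 was listed at 0 in both SL libraries. Of 15 forebrain genes 12 were lower in SLC (12 adjusted over the list alone, camera adjusted p = 2.15e-15), and of 27 HOX genes 22 were higher (23 adjusted over the list alone, camera adjusted p = 5.31e-39). WNT feedback targets were higher for 10 of 15 members and lower for 1 (10 and 1 adjusted over the list alone, camera adjusted p = 9.89e-17), including NKD1 at 2.49 ± 0.594 and 74.1 ± 3.16 TPM. These 3 lists also passed with an estimated correlation, as did the Notch pathway list, of which 3 of 10 genes were lower in SLC (3 adjusted over the list alone, camera adjusted p = 0.00443).

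HES5, a Notch effector of neural progenitors, was at 16 ± 3.97 TPM in SL and 0.143 ± 0.183 TPM in SLC. Neural progenitor genes were lower in SLC for 11 of 23 members and higher for 2 (12 and 2 adjusted over the list alone, camera adjusted p = 1.11e-05, adjusted p = 0.12 with an estimated correlation). In the pan-neuronal list 9 of 27 genes were higher and 4 lower (9 and 4 adjusted over the list alone, camera adjusted p = 0.00297, adjusted p = 0.455 with an estimated correlation). The neurofilament gene NEFL was at 3.79 ± 0.566 and 42.4 ± 0.361 TPM. FOXB1 (1.34 ± 1.1 to 115 ± 22.5 TPM), FZD10 (0.51 ± 0.0283 to 76.2 ± 18.8 TPM) and TMEM132C (0.375 ± 0.29 to 81.2 ± 8.92 TPM) were among the largest differences outside the lists. The limma totals were 356 genes higher and 880 lower in SLC, or 466 and 699 after median-ratio rescaling and 504 and 631 after quantile normalization.

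The next comparisons set each Ngn2-labelled group against its starting cells. No group was sampled at day 2 without the Ngn2 label. Effects of Ngn2 therefore cannot be told apart here from those of time or of any other change in culture. In H9, day 2 brought a proneural and early neuronal programme while pluripotency genes were only partly lowered. DLL3, a Notch ligand induced by proneural factors, rose from 16.6 ± 2.26 to 3597 ± 161 TPM, NHLH1, a helix-loop-helix factor of newborn neurons, from 0.77 ± 0.297 to 199 ± 31.4 TPM, and INSM1, a zinc finger factor of neuronal birth, from 0.56 ± 0.127 to 164 ± 13.1 TPM. Of 27 proneural cascade genes, 24 rose (24 adjusted over the list alone, camera adjusted p = 7.57e-18, adjusted p = 0.0996 with an estimated correlation). Of 27 pan-neuronal genes 17 rose (17 adjusted over the list alone, camera adjusted p = 1.79e-08, adjusted p = 0.149 with an estimated correlation). Among them, the neurofilament gene NEFM went from 12.1 ± 1.16 to 696 ± 31.9 TPM, STMN2, a microtubule regulator of growing axons, from 2.08 ± 0.0354 to 138 ± 23.1 TPM, and ELAVL3, a neuronal RNA-binding protein gene, from 2.24 ± 0.474 to 106 ± 9.2 TPM.

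Genes of peripheral and sensory neurons rose in Ngn2-labelled H9 for 10 of 15 members (10 adjusted over the list alone, camera adjusted p = 2e-04, adjusted p = 0.201 with an estimated correlation). TLX3, a homeobox factor of sensory neurons, went from 0.25 ± 0.0283 to 62.6 ± 19.8 TPM. In the cortical excitatory list 3 of 11 genes rose (3 adjusted over the list alone, camera adjusted p = 0.567). Among them were the vesicular glutamate transporter gene SLC17A7 (3.84 ± 0.735 to 81.9 ± 23.3 TPM) and MEF2C (0.19 ± 0.0707 to 15.6 ± 10.2 TPM). Of 15 forebrain genes 6 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.16), with FEZF1 from 2.05 ± 0.785 to 22.7 ± 2.03 TPM and OTX2 from 19.2 ± 2.21 to 77 ± 26.1 TPM.

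Of 17 pluripotency genes 9 fell in Ngn2-labelled H9 (10 adjusted over the list alone, camera adjusted p = 8.37e-07, adjusted p = 0.0996 with an estimated correlation). NANOG fell from 116 ± 11.8 to 31.3 ± 6.86 TPM and TDGF1 from 570.3 ± 37.8 to 178 ± 19.7 TPM, a call that ended with a pseudocount of 0.1 (adjusted p = 0.14). POU5F1, chosen here after its values were seen, was still at 1014 ± 346 TPM (log2 difference -1.29 ± 0.34, limma adjusted p = 0.011, and 0.061 and 0.083 without H9 replicate 1 or 2, 0.065 with that pseudocount). Of 14 TGF-beta family targets 6 fell and 3 rose (6 and 3 adjusted over the list alone, camera adjusted p = 0.0224, adjusted p = 0.0996 with an estimated correlation). LEFTY1 fell from 309 ± 25 to 25.2 ± 13.4 TPM, and ID4, a helix-loop-helix inhibitor, rose from 1.88 ± 0.247 to 62.6 ± 20.6 TPM. In the surface epithelium list 3 of 10 genes fell and 1 rose (3 and 2 adjusted over the list alone, camera adjusted p = 0.109), EPCAM from 353 ± 1.41 to 141 ± 36.7 TPM. That EPCAM call (limma adjusted p = 0.034) ended without either H9 library (adjusted p = 0.14), with a pseudocount of 0.1 (0.13) and with no filter (0.052). In the fibroblast list 3 of 10 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.967), with ACTA2 from 1.68 ± 0.488 to 24.5 ± 7.45 TPM.

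Outside the lists, ORM1 (0.175 ± 0.247 to 180 ± 102 TPM), SUSD2 (2.12 ± 0.0283 to 409 ± 61 TPM) and the calcium-binding gene S100A1 (2.04 ± 0.325 to 309.7 ± 57.1 TPM) were among the largest rises. The metallothionein gene MT1G (64.3 ± 0.693 to 4.43 ± 1.14 TPM) and TRDN (41.5 ± 1.42 to 2.82 ± 0.878 TPM) were among the largest falls. In the cell cycle list 1 of 20 genes rose and 0 fell in limma (1 and 0 adjusted over the list alone, camera adjusted p = 0.967). In all, limma called 1485 genes higher and 794 lower in Ngn2-labelled H9. The balance of rises and falls depended on the scaling, since median-ratio rescaling gave 1232 and 1106 and quantile normalization 1159 and 1223. Both rescalings bring the libraries to a common centre, so they cannot show which balance is right.

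In SL, Ngn2-labelled libraries also showed the proneural and neuronal genes, with fewer anterior genes. NHLH1 rose from 0.63 ± 0.198 to 309 ± 93.6 TPM, DLL3 from 7.82 ± 0.431 to 1144 ± 567 TPM, and NEUROD4, listed at 0 in both SL libraries, reached 77.7 ± 20.3 TPM. Of 27 proneural genes 23 rose (23 adjusted over the list alone, camera adjusted p = 8.29e-15, adjusted p = 0.104 with an estimated correlation). Of 27 pan-neuronal genes 19 rose and 1 fell (19 and 1 adjusted over the list alone, camera adjusted p = 6.66e-11, adjusted p = 0.104 with an estimated correlation). Among these, STMN2 went from 1.24 ± 0.0566 to 196 ± 59 TPM and the synaptic vesicle gene SYP from 0.61 ± 0.354 to 136 ± 38.3 TPM. Notch effectors rose, HEY1 from 2.1 ± 0.778 to 117 ± 41.8 TPM and HES5 from 16 ± 3.97 to 226 ± 86.7 TPM. Of the 10 Notch pathway genes 6 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.0854).

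Of 15 forebrain genes 5 fell and 2 rose in Ngn2-labelled SL (5 and 2 adjusted over the list alone, camera adjusted p = 0.0158, adjusted p = 0.181 with an estimated correlation). RAX, an eye field factor, went from 95.3 ± 29.8 to 8.82 ± 12.1 TPM and HESX1 from 30.4 ± 13.8 to 1.29 ± 0.616 TPM, while EMX2, a dorsal forebrain factor, rose from 0.175 ± 0.247 to 11.2 ± 3.39 TPM. Neural progenitor genes moved both ways, with 4 of 23 higher and 8 lower (4 and 8 adjusted over the list alone, camera adjusted p = 0.113), and SOX21 fell from 132 ± 21.1 to 12.2 ± 12.3 TPM. Of 17 pluripotency genes 8 fell (8 adjusted over the list alone, camera adjusted p = 3.17e-05, adjusted p = 0.104 with an estimated correlation), POU5F1 from 13.2 ± 1.25 to 1.3 ± 1.12 TPM. In the peripheral and sensory list 6 of 15 rose (7 adjusted over the list alone, camera adjusted p = 0.0792), with ISL1, listed at 0 in SL, at 15.4 ± 8.44 TPM. In the motor and monoaminergic list 4 of 5 rose (4 adjusted over the list alone, camera adjusted p = 0.0268, adjusted p = 0.211 with an estimated correlation).

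TGF-beta family targets rose in Ngn2-labelled SL for 10 of 14 members (10 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.02, adjusted p = 0.104 with an estimated correlation). SMAD7, a feedback inhibitor, rose from 1.6 ± 0.396 to 24.3 ± 8.81 TPM. Neural crest genes rose for 7 of 11 and fell for 1 (8 and 2 adjusted over the list alone, camera adjusted p = 0.185), among them TFAP2A (0.095 ± 0.0354 to 11.4 ± 3.75 TPM) and MSX2 (0.12 ± 0.0283 to 13 ± 9.03 TPM). Fibroblast and mesenchyme genes rose for 6 of 10 (6 adjusted over the list alone, camera adjusted p = 0.0792), with COL1A1, a collagen gene, from 13.7 ± 2.14 to 322 ± 103 TPM. The stress list had 7 of 17 higher (7 adjusted over the list alone, camera adjusted p = 0.0732), among them GDF15 (3.98 ± 0.509 to 392 ± 298 TPM), CDKN1A, the p21 cell cycle inhibitor (39.7 ± 2.5 to 573 ± 227 TPM), and MDM2 (10.7 ± 4.02 to 58.5 ± 2.51 TPM). In the surface epithelium list 3 of 10 fell and 1 rose (3 and 1 adjusted over the list alone, camera adjusted p = 0.0137, adjusted p = 0.405 with an estimated correlation).

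The neuropeptide gene SST (0.115 ± 0.163 to 245 ± 123 TPM), MFAP4 (0.85 ± 0.594 to 504 ± 126 TPM) and CPLX2, a regulator of vesicle release (0.075 ± 0.0212 to 156 ± 40.1 TPM), were among the largest rises outside the lists in SL. RAB25 (30.6 ± 3.83 to 0.13 ± 0.121 TPM) and the interferon-induced genes IFITM1 (387 ± 11.5 to 16.5 ± 11.8 TPM) and BST2 (191 ± 118 to 7.58 ± 5.35 TPM) were among the largest falls. The limma totals were 1961 genes higher and 904 lower, or 1525 and 1255 after median-ratio rescaling and 1423 and 1392 after quantile normalization.

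In SLC, Ngn2-labelled libraries gained proneural and Notch genes and lost WNT-responsive genes. NHLH1 rose from 0.763 ± 0.393 to 208 ± 81 TPM, GADD45G, a growth-arrest gene of newborn neurons, from 0.443 ± 0.211 to 151 ± 68.8 TPM, and DCX, a microtubule protein gene of migrating neurons, from 0.5 ± 0.24 to 52.8 ± 18.7 TPM. HES5 rose from 0.143 ± 0.183 to 299 ± 136 TPM and HEYL from 1.26 ± 0.434 to 177 ± 103 TPM. Of 10 Notch pathway genes 7 rose (7 adjusted over the list alone, camera adjusted p = 0.00156, adjusted p = 0.042 with an estimated correlation). SP5 fell from 194 ± 27 to 2.36 ± 2.14 TPM and CDX2 from 203 ± 95 to 19.5 ± 7.97 TPM. Of 15 WNT feedback targets 8 fell while 3 rose (8 and 3 adjusted over the list alone, camera adjusted p = 8.46e-06, adjusted p = 0.042 with an estimated correlation). APCDD1, a WNT inhibitor in that list, went the other way, from 18.6 ± 12.7 to 164 ± 75.1 TPM. FGF17 fell from 198 ± 71 to 0.373 ± 0.169 TPM and FGF8 from 177 ± 53.8 to 7.22 ± 4.87 TPM. Of 8 midbrain and isthmus genes 3 fell and 1 rose (3 and 1 adjusted over the list alone, camera adjusted p = 0.0707).

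Of 27 proneural genes 26 rose in Ngn2-labelled SLC (26 adjusted over the list alone, camera adjusted p = 1.03e-12, adjusted p = 0.145 with an estimated correlation). Of 27 pan-neuronal genes 19 rose and 1 fell (19 and 1 adjusted over the list alone, camera adjusted p = 0.000215, adjusted p = 0.308 with an estimated correlation). Neural progenitor genes rose for 15 of 23 members (15 adjusted over the list alone, camera adjusted p = 0.00815, adjusted p = 0.308 with an estimated correlation). NES, an intermediate filament gene of progenitors, rose from 144 ± 17.8 to 1382 ± 316 TPM and PAX6 from 0.263 ± 0.135 to 10.2 ± 5.25 TPM. HOX genes moved both ways, 11 of 27 higher and 3 lower (11 and 3 adjusted over the list alone, camera adjusted p = 0.743), with HOXA5 from 2.16 ± 1.26 to 21.1 ± 2.42 TPM. Neural crest genes rose for 7 of 11 and fell for 2 (7 and 2 adjusted over the list alone, camera adjusted p = 0.492), among them TFAP2B (0.03 ± 0.0361 to 20.3 ± 11.4 TPM) and PAX3 (6.05 ± 3.85 to 59.7 ± 44.4 TPM). In the GABAergic list 2 of 7 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.743), the fall being GAD1, which makes the transmitter GABA, from 19.2 ± 8.07 to 2.13 ± 0.535 TPM.

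Of the other-cell-type lists in SLC, 5 of 10 fibroblast genes rose (5 adjusted over the list alone, camera adjusted p = 0.492), TAGLN, an actin-binding smooth muscle gene, from 39.2 ± 2.99 to 937 ± 45.9 TPM. Of 7 mesoderm and endoderm genes 2 fell (2 adjusted over the list alone, camera adjusted p = 0.0139, adjusted p = 0.145 with an estimated correlation). Of 10 surface epithelium genes 2 fell (2 adjusted over the list alone, camera adjusted p = 0.0226, adjusted p = 0.483 with an estimated correlation). Pluripotency genes fell for 3 of 17 members (3 adjusted over the list alone, camera adjusted p = 0.00117, adjusted p = 0.145 with an estimated correlation). PCDH8, a protocadherin gene (0.12 ± 0.0624 to 178 ± 47.7 TPM), the dopamine receptor gene DRD2 (0.09 ± 0.0173 to 135 ± 73.8 TPM) and PPP1R17 (0.22 ± 0.183 to 106 ± 50.1 TPM) were among the largest rises outside the lists. HES3 (300 ± 67.1 to 3.87 ± 5.29 TPM) and the lactate transporter gene SLC16A3 (136 ± 9.98 to 2.24 ± 0.647 TPM) were among the largest falls. The limma totals were 2679 genes higher and 603 lower. Median-ratio rescaling gave 1494 and 1225 and quantile normalization 1343 and 1292, so the size of the excess of rises depended on the scaling. Both rescalings bring the libraries to a common centre, which by itself moves rises and falls towards balance. The median log2 difference over all genes was 0.363 as deposited and 0.012 after median-ratio rescaling.

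**Figure D2:**
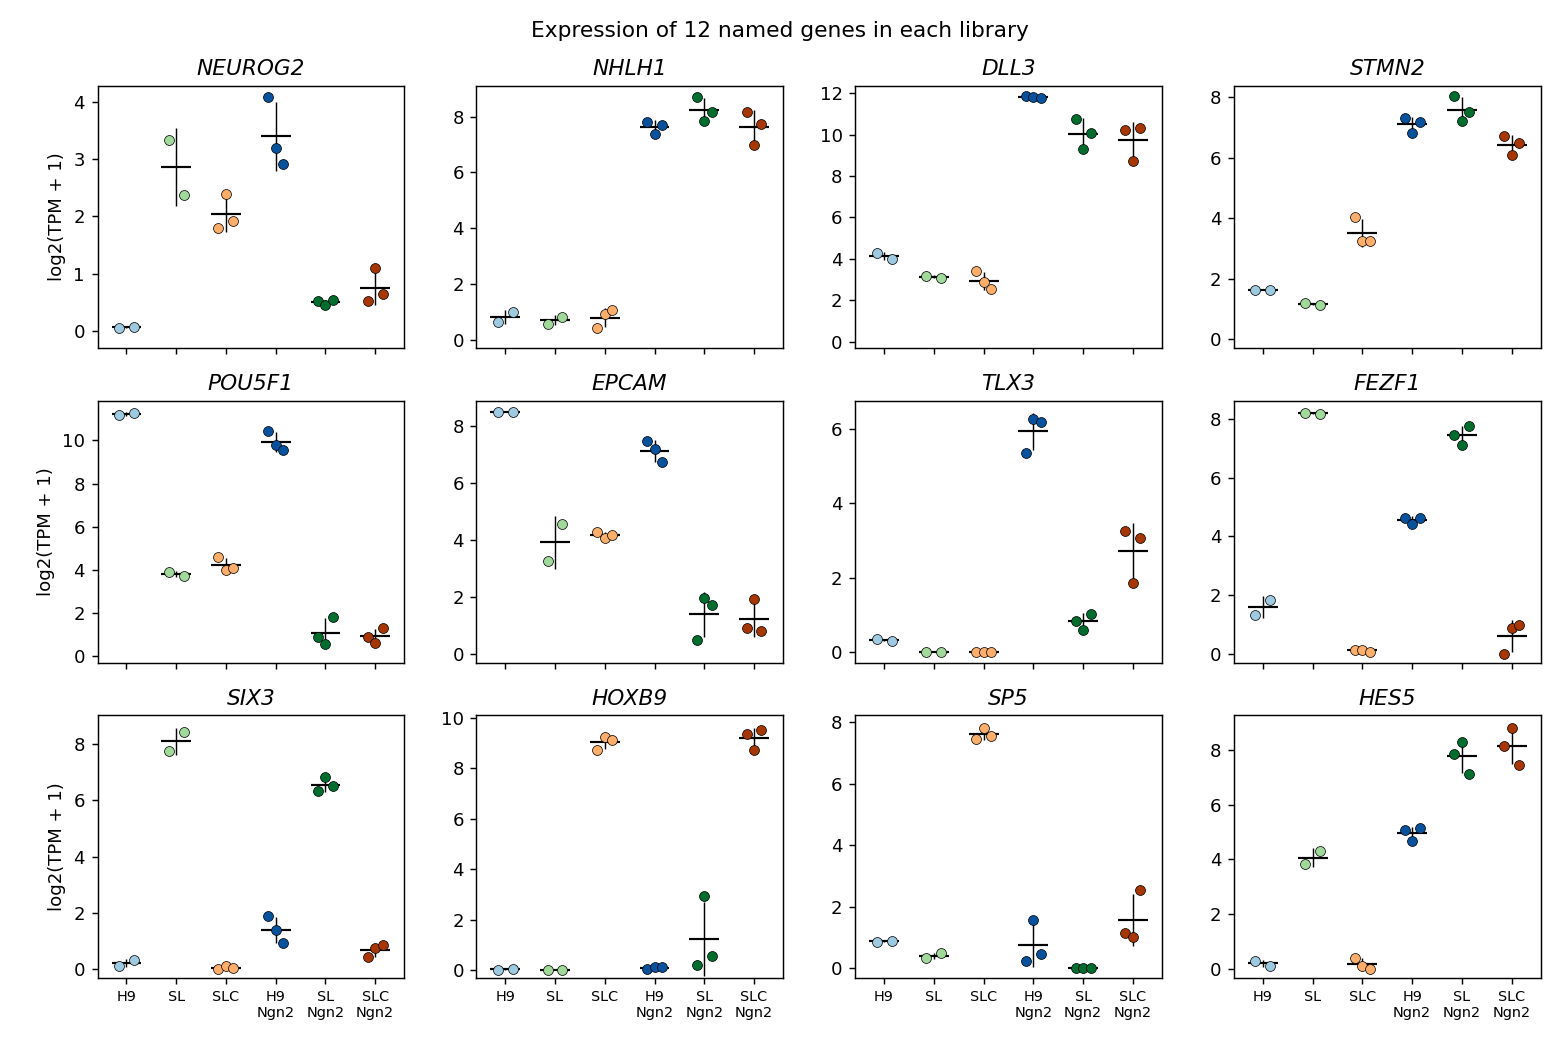
Expression of 12 named genes, as log2(TPM + 1) on the vertical axis, in the 6 groups on the horizontal axis. Each point is 1 library, the line is the group mean and the bar the SD; NHLH1, DLL3 and STMN2 are higher in every Ngn2-labelled library than in the starting cells, while FEZF1, SIX3 and HOXB9 separate SL from SLC before and after.

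The 3 responses, in which Ngn2 and time in culture are not separated, shared many genes. Limma called 598 genes higher and 103 lower in all 3, where independent lists of the same sizes would share 33.6 and 1.9. Each response set its own libraries against each other, but all 3 used the same estimate of each gene's spread. The calls are therefore not fully independent, and the numbers for independent lists are only a reference. The 2 responses of the drug-derived populations had 1387 rises and 317 falls in common, against 344.9 and 35.8 for independent lists, and H9 shared 729 rises with SL and 832 with SLC, against 191.2 and 261.2. Across the 15230 genes tested, which are not independent replicates, the Pearson correlation of the log2 differences was 0.726 between SL and SLC, 0.497 between H9 and SL and 0.491 between H9 and SLC. NHLH1 and DLL3 were among the genes that rose in all 3 responses. Median-ratio rescaling gave 439 shared rises and 190 shared falls, and quantile normalization 403 and 220.

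The Ngn2-labelled groups were then compared with each other at day 2. Ngn2-labelled SL cells had higher levels of several forebrain factors than Ngn2-labelled H9 cells, and less of the sensory factor TLX3. SIX3 was at 94 ± 17.2 TPM in Ngn2-labelled SL and 1.74 ± 0.888 TPM in Ngn2-labelled H9, PAX6 at 33.5 ± 13.1 and 0.51 ± 0.125 TPM, and SP8, a forebrain zinc finger factor, at 24.8 ± 9.22 and 0.637 ± 0.316 TPM. TLX3 was at 0.777 ± 0.27 TPM in Ngn2-labelled SL against 62.6 ± 19.8 TPM in Ngn2-labelled H9. Forebrain genes were higher in SL for 10 of 15 members and lower for 2 (10 and 2 adjusted over the list alone, camera adjusted p = 0.000644, adjusted p = 0.124 with an estimated correlation). In the peripheral and sensory list 6 of 15 were lower and 1 higher (6 and 1 adjusted over the list alone, camera adjusted p = 0.0433, adjusted p = 0.49 with an estimated correlation).

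Proneural genes went both ways, with 7 of 27 members higher and 2 lower in Ngn2-labelled SL than in Ngn2-labelled H9 (7 and 2 adjusted over the list alone, camera adjusted p = 0.623). BHLHE22, a factor of cortical and spinal neurons, was at 34 ± 16.1 against 1.34 ± 0.688 TPM and NEUROD1 at 40.1 ± 13.2 against 6 ± 3.97 TPM, while INSM1 was at 43.3 ± 12.9 against 164 ± 13.1 TPM. NEFM was lower in SL (131 ± 61.8 against 696 ± 31.9 TPM) and MAP2, a dendritic microtubule gene, higher (92.4 ± 19 against 17.8 ± 3.8 TPM). SST (245 ± 123 against 6.29 ± 5.05 TPM), the axonal adhesion gene CNTN2 (184 ± 129 against 3.49 ± 2.39 TPM) and VSX1 (34.7 ± 9.94 against 0.183 ± 0.119 TPM) were among the largest differences. Of 17 pluripotency genes 15 were lower in SL (15 adjusted over the list alone, camera adjusted p = 7.42e-21), which also held with an estimated correlation. The surface epithelium list had 6 of 10 lower and 1 higher (6 and 1 adjusted over the list alone, camera adjusted p = 0.000179, adjusted p = 0.284 with an estimated correlation), EPCAM at 1.89 ± 1.32 against 141 ± 36.7 TPM. Fibroblast genes were higher for 6 of 10 and lower for 1 (6 and 1 adjusted over the list alone, camera adjusted p = 0.0706), ACTA2 at 336 ± 88.2 against 24.5 ± 7.45 TPM. The limma totals were 1176 genes higher and 877 lower in SL, or 899 and 1005 after median-ratio rescaling.

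Ngn2-labelled SLC cells differed from Ngn2-labelled H9 cells by posterior HOX and neural progenitor genes and by lower sensory genes. HOXB9 was at 603 ± 157 TPM against 0.07 ± 0.0265 TPM and HOXB6 at 54.1 ± 8.23 against 0.0233 ± 0.0404 TPM. In total 25 of 27 HOX genes were higher (27 adjusted over the list alone, camera adjusted p = 1.38e-19, adjusted p = 0.106 with an estimated correlation). OTX2, a head organiser factor, was at 0.77 ± 0.495 against 77 ± 26.1 TPM and FEZF1 at 0.61 ± 0.535 against 22.7 ± 2.03 TPM, among 4 of 15 forebrain genes that were lower with 2 higher (4 and 2 adjusted over the list alone, camera adjusted p = 0.0263, adjusted p = 0.188 with an estimated correlation). TLX3 was at 6.16 ± 3.13 against 62.6 ± 19.8 TPM, among 7 of 15 peripheral and sensory genes that were lower with 1 higher (7 and 2 adjusted over the list alone, camera adjusted p = 0.00938, adjusted p = 0.332 with an estimated correlation). SYP was at 24.5 ± 9.2 against 126 ± 12.2 TPM, SLC17A7 at 3.59 ± 2.58 against 81.9 ± 23.3 TPM, and the calcium-binding gene CALB1 at 0.28 ± 0.225 against 125 ± 26.4 TPM.

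Neural progenitor genes were higher in Ngn2-labelled SLC than in Ngn2-labelled H9 for 15 of 23 members (15 adjusted over the list alone, camera adjusted p = 6.38e-07, adjusted p = 0.106 with an estimated correlation), SOX1 at 36.7 ± 30.6 against 0.6 ± 0.303 TPM. Notch genes were higher for 7 of 10 and lower for 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.0263, adjusted p = 0.106 with an estimated correlation). Of 17 pluripotency genes 15 were lower (15 adjusted over the list alone, camera adjusted p = 1.38e-19), and 7 of 10 surface epithelium genes were lower (8 adjusted over the list alone, camera adjusted p = 7.88e-07, adjusted p = 0.12 with an estimated correlation). The pluripotency list also passed with an estimated correlation. The limma totals were 1217 genes higher and 1079 lower, or 898 and 1243 after median-ratio rescaling.

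Between Ngn2-labelled SLC and SL the head-to-trunk difference of the starting cells was still present. FEZF1 was at 0.61 ± 0.535 TPM in SLC and 175 ± 37.5 TPM in SL, OTX2 at 0.77 ± 0.495 and 178 ± 41.2 TPM, and HOXB9 at 603 ± 157 and 2.42 ± 3.64 TPM. Forebrain genes were lower in SLC for 8 of 15 members (8 adjusted over the list alone, camera adjusted p = 1.12e-16), HOX genes higher for 25 of 27 (27 adjusted over the list alone, camera adjusted p = 1.32e-62), and WNT feedback targets higher for 6 of 15 (8 adjusted over the list alone, camera adjusted p = 2.11e-08). These 3 lists also passed with an estimated correlation. CDX2 was at 19.5 ± 7.97 TPM in SLC and 0.17 ± 0.157 TPM in SL. Pan-neuronal genes were lower in SLC for 4 of 27 (5 adjusted over the list alone, camera adjusted p = 3.69e-06, adjusted p = 0.245 with an estimated correlation), SYP at 24.5 ± 9.2 and 136 ± 38.3 TPM. GABAergic list genes were lower for 3 of 7 (4 adjusted over the list alone, camera adjusted p = 4.58e-05, adjusted p = 0.0516 with an estimated correlation), among them LHX5, a factor of early interneurons, at 3.75 ± 1.53 and 22.1 ± 5.64 TPM. ATOH7, a proneural factor of retinal ganglion cells, was at 0.747 ± 0.345 and 47.1 ± 17.3 TPM, and FOXB1 at 20.8 ± 10.1 and 0.0833 ± 0.144 TPM.

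Neural crest genes were higher in Ngn2-labelled SLC than SL for 3 of 11 members (5 adjusted over the list alone, camera adjusted p = 0.00471, adjusted p = 0.298 with an estimated correlation), with TFAP2B at 20.3 ± 11.4 and 1.55 ± 1.05 TPM. Limma called 226 genes higher and 304 lower in SLC, 530 in all, and 131 when these 6 libraries were fitted alone, where 14 calls of named genes ended, among them TFAP2B, SLC17A7 and TLX3 (adjusted p = 0.073, 0.065 and 0.11). Replicate numbers paired these 6 libraries, and a fit of them alone with the replicate block called 422 genes, 166 higher and 256 lower. With that block the FOXD3 difference of 2.04 ± 0.59 and the SYT4 difference of -1.86 ± 0.34 no longer passed (limma adjusted p = 0.13 and 0.061), and neither did the neural crest list (camera adjusted p = 0.062). The proneural and surface epithelium lists, both lower in SLC, passed there (camera adjusted p = 0.048 each, adjusted p = 0.48 each with an estimated correlation) but not in the fit of all 16 libraries (camera adjusted p = 0.0902 and 0.0914). With an estimated correlation no list passed in the fit of these 6 libraries with the block, HOX and forebrain genes included (adjusted p = 0.34 and 0.36).

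The last comparisons tested whether the change from starting to Ngn2-labelled cells differed between populations, as a difference of log2 differences. Larger and smaller refer here to the value with its sign, so a smaller log2 difference can be a fall set against a rise. Starting levels enter these values, so a larger difference need not mean a higher level at day 2. In the H9 and SL responses TGF-beta family targets had medians of opposite sign (log2 difference -1.12 and 1.693), and so had forebrain genes (0.5 and -0.744). TGF-beta family targets had larger log2 differences in SL for 9 of 14 members and smaller ones for 1 (9 and 2 adjusted over the list alone, camera adjusted p = 0.00015, adjusted p = 0.0201 with an estimated correlation). Before Ngn2, 11 of these 14 were lower in SL than in H9 and 2 higher. At day 2, 1 was higher and 2 lower in Ngn2-labelled SL (1 and 2 adjusted over the list alone, camera adjusted p = 0.403). CER1, a secreted BMP and Nodal antagonist, differed by 6.35 ± 0.70 (limma adjusted p = 6.4e-05), falling from 26.9 ± 3.03 to 3.73 ± 3.93 TPM in H9 and rising from 0.295 ± 0.148 to 13.9 ± 4.39 TPM in SL. Forebrain genes were smaller for 8 of 15 and larger for 1 (9 and 1 adjusted over the list alone, camera adjusted p = 0.00015, adjusted p = 0.0616 with an estimated correlation), FEZF1 by -3.72 ± 0.38 (limma adjusted p = 4e-05). Neural progenitor genes were smaller for 8 of 23 and larger for 1 (9 and 1 adjusted over the list alone, camera adjusted p = 0.000172, adjusted p = 0.244 with an estimated correlation). Pan-neuronal genes were larger for 10 of 27 and smaller for 2 (11 and 2 adjusted over the list alone, camera adjusted p = 0.0329, adjusted p = 0.611 with an estimated correlation). TLX3, listed at 0 in both SL starting libraries, differed by -4.80 ± 0.50 in log2(TPM + 1) values (limma adjusted p = 4.1e-05), and SST by 6.65 ± 0.67 (limma adjusted p = 3.6e-05). Limma called 1183 genes with a larger and 908 with a smaller difference, 2091 in all, and 1382 without H9 replicate 2.

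In the H9 and SLC responses TGF-beta family targets (median log2 difference -1.12 and 1.109) and WNT targets (0.28 and -1.003) also had medians of opposite sign. TGF-beta family targets were larger for 10 of 14 members (10 adjusted over the list alone, camera adjusted p = 0.000562, adjusted p = 0.0229 with an estimated correlation), LEFTY1 by 4.76 ± 0.60 (limma adjusted p = 0.00018). LEFTY1 fell in H9, as given above, and was at 0.0233 ± 0.0404 and 1.44 ± 1.41 TPM in SLC before and after. Before Ngn2, 11 of the 14 TGF-beta family targets were lower in SLC than in H9. At day 2, 5 were lower and 1 higher in Ngn2-labelled SLC (6 and 2 adjusted over the list alone, camera adjusted p = 0.106). WNT feedback targets were smaller for 7 of 15 (7 adjusted over the list alone, camera adjusted p = 3.75e-06, adjusted p = 0.0229 with an estimated correlation), SP5 by -5.90 ± 0.55 (limma adjusted p = 1.6e-05). Midbrain and isthmus genes were smaller for 3 of 8 and larger for 1 (5 and 1 adjusted over the list alone, camera adjusted p = 0.000562, adjusted p = 0.0365 with an estimated correlation), with FGF17 at -7.14 ± 0.38 (limma adjusted p = 2.8e-07). EMX1 differed by 1.46 ± 0.28 (limma adjusted p = 0.0026), its level in SLC being 0.0167 TPM before and 0.0767 TPM after. The calls for FEZF1 and TLX3 in this comparison ended with a pseudocount of 0.1 (adjusted p = 0.11 and 0.074). Limma called 1654 genes with a larger and 715 with a smaller difference, 2369 in all, and 1526 without H9 replicate 2. Median-ratio rescaling gave 1229 and 1047, and quantile normalization 1161 and 1063.

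Between the SLC and SL responses, progenitor and Notch genes had larger log2 differences in SLC and neuronal and WNT-responsive genes smaller ones. The median was 1.399 in SLC and 0.026 in SL for neural progenitor genes, and -1.003 and 0.411 for WNT feedback targets. Neural progenitor genes were larger for 12 of 23 members (16 larger and 1 smaller adjusted over the list alone, camera adjusted p = 1.17e-09, adjusted p = 0.0439 with an estimated correlation), SOX3 by 4.53 ± 0.62 (limma adjusted p = 0.00075). Notch genes were larger for 4 of 10 and smaller for 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.00128, adjusted p = 0.0383 with an estimated correlation), HES5 by 4.26 ± 0.48 (limma adjusted p = 0.00015). Forebrain genes were larger for 5 of 15 (8 adjusted over the list alone, camera adjusted p = 0.000286, adjusted p = 0.0476 with an estimated correlation). HESX1 differed by 3.59 ± 0.36 (limma adjusted p = 6.4e-05); it fell in SL from 30.4 ± 13.8 TPM and started at 0.993 ± 0.182 TPM in SLC. WNT feedback targets were smaller for 8 of 15 and larger for 1 (10 and 3 adjusted over the list alone, camera adjusted p = 1.17e-09, adjusted p = 0.0112 with an estimated correlation). Pan-neuronal genes were smaller for 11 of 27 and larger for 1 (11 and 1 adjusted over the list alone, camera adjusted p = 8.6e-10, adjusted p = 0.1 with an estimated correlation), STMN2 by -3.49 ± 0.37 (limma adjusted p = 9.4e-05). Starting levels already differed. Before Ngn2, Notch genes were lower in SLC than in SL for 3 of 10 members and forebrain genes for 12 of 15. Pan-neuronal genes were then higher for 9 of 27 and lower for 4. At day 2, 0 of 10 Notch genes passed, and forebrain genes were still lower in SLC for 8 of 15. Pan-neuronal genes were then lower for 4 of 27. A larger difference in SLC thus need not mean a higher level at day 2. Limma called 568 genes with a larger and 262 with a smaller difference, 830 in all. There were 455 without SL replicate 3 and 529 when the groups concerned were fitted alone. Median-ratio rescaling gave 425 and 352, and quantile normalization 426 and 374.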

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

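The tests on pluripotency genes and on NEUROG2 were written only after the results they concern had been seen; the mixing test was written before its result. Each value below is a difference between the responses of 2 populations in log2(TPM + 1), tested in limma as such, and is given because that difference passed the thresholds. The 54 values belong to genes named by the rule.

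Between the SL and H9 responses, the difference was -5.70 for NEUROG2, -3.58 for VRTN, -5.86 for SOX21, -4.53 for RAX, -3.72 for FEZF1 and -3.55 for HESX1. The sensory factor TLX3, listed at 0 in the SL starting cells, differed by -4.80. Neuronal genes differed by 3.85 (BHLHE22, listed at 0 in both starting populations), 3.85 (L1CAM) and -3.20 (MAP2). TGF-beta targets differed by 6.35 (CER1) and 5.09 (LEFTY1), and stress genes by 5.77 (GDF15) and 3.48 (CDKN1A). KRT19 differed by -4.19, SST by 6.65, PMEPA1 by 5.73 and ORM1 by -8.19.

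Between the SLC and H9 responses, the difference was -4.62 for NEUROG2, 1.46 for EMX1, 3.63 for EMX2, -2.48 for FEZF1, -7.14 for FGF17 and 2.89 for HOXA5. Neural crest factors differed by 4.40 (FOXD3) and 4.18 (TFAP2B, listed at 0 in the H9 starting cells), and TLX3, listed at 0 in the SLC starting cells, by -2.89. Neuronal genes differed by -5.08 (NCAM1), -3.78 (NEFM) and -2.97 (SLC17A7). HES5 differed by 3.21, the WNT targets SP5 and NKD1 by -5.90 and -3.37, LEFTY1 by 4.76, TAGLN by 5.80 and DDIT4 by -3.47.

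Between the SLC and SL responses, the difference was 1.43 for EMX1, 4.53 for SOX3, 3.37 for SOX9, 4.07 for RAX, 3.59 for HESX1, -6.90 for FGF17 and 2.75 for HOXA5. Neuronal genes differed by -3.49 (STMN2), -3.10 (SYP) and -3.45 (GAD1), Notch effectors by 4.26 (HES5) and 2.73 (HES4). SP5, listed at 0 in the Ngn2-labelled SL libraries, differed by -5.61 and CDX2 by -3.38. COL1A1 differed by -2.95, CDKN1A by -2.40, GDF15 by -3.99 and ATOH7 by -5.04. The calls for RAX, COL1A1 and GDF15 ended when the groups concerned were fitted alone (limma adjusted p = 0.052, 0.1 and 0.088), and that for HOXA5 with a pseudocount of 0.1 (limma adjusted p = 0.075). The RAX call also ended without SL replicate 1 (limma adjusted p = 0.051). Those for COL1A1 and GDF15 also ended with no filter (limma adjusted p = 0.062 and 0.053) and without some single libraries (limma adjusted p up to 0.15 and 0.1).

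Pluripotency genes kept a median of 0.495 of their H9 level in Ngn2-labelled H9, from 0.132 for DPPA2 to 1.34 for PRDM14. RNA of unchanged H9 cells as the whole of what POU5F1 kept would leave no gene far below its share, and 1 of the other pluripotency genes (DPPA2) lay wholly below, too few to decide. A second test, written after the first, counted genes with at least 50 TPM in H9 whose shares all lay below 0.5 of the pluripotency median. It found 12, under the 20 it required, so by its own rule it did not decide. POU5F1 kept at least 0.316 in each library. The 12 genes were picked for shares below 0.247, so their place below POU5F1 was fixed by that choice. MT1X, at 662 TPM in H9, kept at most 0.129, LEFTY1 at most 0.13, VSNL1 at most 0.142 and MYC at most 0.204. These 12 genes are the lowest of 2869. They include metallothionein genes, whose values are uncertain, and SNORA64, a small RNA listed at 0 in Ngn2-labelled H9. They therefore do not decide whether wholly unchanged cells were the only source of the POU5F1 that remained. Such cells as the whole or a part of that source stay open. The cells were sorted by fluorescence, with no gate given, so whether the sort removed unchanged cells is unknown. A slow loss of pluripotency transcripts in converting cells was not tested.

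NEUROG2 was lower in the Ngn2-labelled SL and SLC libraries than in their starting cells. The proneural list, which does not hold NEUROG2, rose there by a median of at least 3.4 log2 units. This rise, already known when the test was written, argues against an exchange of starting and Ngn2-labelled libraries in SL and SLC. Transcripts of the introduced factor counted under NEUROG2 in all 3 Ngn2-labelled groups stay open. NEUROG2 was not listed at 0 in any of these groups, the highest library of the lowest group (SL) being at 0.45 TPM. A fall of the cells' own transcripts could hide those of the introduced factor, but in Ngn2-labelled SL these could not exceed 0.45 TPM. No biological explanation was tested.

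The libraries numbered 2 of Ngn2-labelled SL and SLC lay nearer their starting cells on the first principal component, at 49.6 and 41.1 against 73.1 and 75.9 (SL) and 66.6 and 66.7 (SLC). Starting-cell RNA mixed into a library would give 1 share for rising and falling genes alike. In SL the shares were 0.45 and 0.14, a difference of 0.3 (95% interval 0.28 to 0.33). Each interval resampled the genes of 1 library, so it holds no spread between libraries. The SL difference met the rule set beforehand against simple mixing. The genes were chosen on the other libraries, however, which may shift the shares of rising and falling genes unequally. Simple mixing as the whole cause is therefore not excluded. In SLC the shares were 0.3 and 0.13, a difference of 0.17 (0.15 to 0.21), which leaves mixing open there as well. A slower response in these libraries was not tested.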

How the results depend on the processing

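The fit without both libraries numbered 2, the paired fit of 6 libraries alone and the alternatives for the overlap were chosen after the data had been seen. Of 7410 tests of named genes under an alternative, 7333 kept their call, 75 lost it, 2 gained it and 0 reversed; 32 of 299 calls were lost under at least 1 alternative. Of the 7333 kept calls, 4890 came from leaving out 1 library, often one outside the groups compared. Leaving out such a library cannot move the log2 difference and changes only the shared spread. The share of kept calls therefore overstates how robust the calls are. Rescaling ended only SP8 (SLC response, log2 difference 0.98 by median ratio). Of 2025 list tests 1839 kept their call, 132 lost it and 54 gained it. With an estimated correlation 26 of 88 list calls were left. Of the list calls in the report, 5 were lost with median-ratio rescaling and with quantile normalization alike: TGF-beta targets in the H9 response (camera adjusted p = 0.072 and 0.091), mesoderm and endoderm (0.15 and 0.14) and surface epithelium (0.16 and 0.2) in the SLC response, and, against Ngn2-labelled H9, forebrain genes in SLC (0.12 and 0.17) and sensory genes in SL (0.098 and 0.1). Median-ratio rescaling also ended sensory genes in SLC there (0.053). The sensory call in SL was lost as well with no filter (0.065), in its own groups alone (0.11) and with the replicate block (0.056). Higher or no filters, another pseudocount, own groups or the block ended further calls. These were surface epithelium in SL against H9 (0.07 with a pseudocount of 0.1, 0.11 in own groups, 0.057 with the block) and forebrain genes in the SL response (0.066 with that pseudocount, 0.06 at 5 TPM). In the SL response TGF-beta targets (0.06 at 5 TPM) and the motor list (0.14 with no filter, 0.082 at 5 TPM) were lost too. So were Notch genes between Ngn2-labelled SLC and H9 (0.061 in own groups) and pan-neuronal genes between the SL and H9 responses (0.056 with no filter). The mesoderm and endoderm list has no members at 5 TPM, so it has no value there.

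Own groups alone gave 131 genes against 530 between Ngn2-labelled SLC and SL, and 529 against 830 for the difference between the SLC and SL responses; both fits have fewer samples. Leaving out 1 library gave 1382 (H9 replicate 2) to 2248 genes for SL against H9 responses, 1526 (H9 replicate 2) to 2534 for SLC against H9, and 455 (SL replicate 3) to 910 for SLC against SL. The response counts ranged over 1748 to 2595 (H9), 2204 to 3293 (SL) and 2773 to 3617 (SLC), and the overlap over 520 to 775. Starting cells ranged over 2956 to 3473, 3192 to 3670 and 859 to 1286 genes, and Ngn2-labelled groups over 1894 to 2220, 2190 to 2438 and 430 to 669.

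A replicate block on all 16 libraries gave 2209, 3074 and 3302 genes for the responses and 570 between Ngn2-labelled SLC and SL. In the paired comparison, the block on its 6 libraries changed no gene call other than those given in the report, and no other list call at the preset correlation. Splits of 6 libraries into 3 and 3 were made for 4 comparisons. In each, 1 of 10 splits, the real one, had as many genes (3282, 2053, 2296 and 530, against at most 3, 1, 1 and 74 in the others), and 10 splits cannot give a share under 0.05. These splits ignore the pairs of the last comparison. Its 3 other splits that part all 3 pairs gave 0 genes, and the 74 came from a split that parts 1 pair. TPM keeps no depth, so how far depth limits low genes is unknown.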

Other observations

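The p53 and eye field lists were written down after the genes that prompted them had been seen, and those genes were left out of the tests. What each outcome would mean was written before the other members were examined. GDF15, CDKN1A and MDM2, which are p53 targets, were higher in Ngn2-labelled SL cells, and 20 other p53 targets were therefore tested. In the SL response 15 of the 20 rose, with a median log2 difference of 1.31. Camera gave p = 0.033 with an estimated correlation (0.22 adjusted over 24 tests) and p = 4.1e-07 with the preset one, not adjusted. With the estimated correlation the list does not pass correction. PLK3 went from a mean of 6.73 to 94.16 TPM, TP53INP1 from 11.31 to 62.42 TPM and PHLDA3 from 25.48 to 295.4 TPM in SL. The median of these p53 targets was 0.71 in SLC, where 6 rose, and 0.2 in H9, where 5 rose. With an estimated correlation camera gave p = 0.34 for SLC and p = 0.54 for H9 (0.039 and 0.2 with the preset one, not adjusted). Before Ngn2 these targets had a median log2 difference of 0.66 between SLC and SL, with 5 of 20 higher in SLC. Camera gave p = 0.011 with an estimated correlation (0.22 adjusted over 24 tests) and p = 1.3e-10 with the preset one, not adjusted. Between Ngn2-labelled SLC and SL the median was 0.08 and 0 of 20 passed. The SLC response minus the SL response had a median of -0.76, with 2 of 20 smaller. Camera gave p = 0.02 with an estimated correlation (0.22 adjusted over 24 tests) and p = 1.4e-08 with the preset one, not adjusted. By construction this difference of responses is the day 2 difference minus the starting difference. Neither it nor the starting difference passes correction with an estimated correlation.

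SIX3, SIX6 and RAX marked the SL starting cells, and 8 other eye field and retina genes were tested between SLC and SL. The list had 18 members, of which 5 had been seen before and only these 8 others were among the genes tested. Their median log2 difference was -0.05 (camera p = 0.82 with an estimated correlation) and 0 of 8 passed. TBX3, ALDH1A3, ALDH1A1, MAB21L1 and SFRP5 had means of at most 0.39 TPM in both populations. Such levels leave little room for a difference in log2(TPM + 1), so the median decides little and a wider eye field difference stays open. Among the 8 genes tested, OPTC was at a mean of 7.05 TPM in SL and 4.36 TPM in SLC, and VAX2 at 1.865 and 1.953 TPM.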
